A study of Mus musculus with 12 samples.

How the data were processed

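The 12 samples of the series fall into FMRP iCLIP and RNA-seq, wild type and Mettl3 knockout, with 3 replicates each; 6 iCLIP libraries were analysed and RNA-seq was not used here. In iCLIP, ultraviolet light (150 mJ per square cm, per the labels) links protein to RNA, and reverse transcription stops near the link, so the nucleotide before a tag marks the crosslink. Each file was matched to the iCLIP sample of the same genotype and replicate by name. The files do not name an antibody: their barcodes and copy numbers are those of a crosslinking library, and an m6A crosslinking library would look alike, so the assignment to FMRP rests on the labels.

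The deposited files list 1 unique tag per line with position, strand and a name that holds a random barcode and a copy number. The authors also deposited a score per tag, which was not used in any test. BWA 0.7.1 and the build mm10 are named in the submitters' processing notes; the collapsing tool is not given in the sources used here. Tags were 17 to 40 nt long and aligned in 1 block, so RNA that crosses a splice junction is missed or cut short, which lowers the yield from short exons. The mean number of reads behind a tag was 1.53 to 1.63 per wild-type and 1.54 to 1.56 per knockout library.

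Crosslinks were assigned to gene spans of GRCm38.p6, the assembly of mm10. The annotation used here had spans and no strand, exons or sequence. A gene's strand was taken from the pooled tags of all libraries, where at least 30 tags fell on it and 80% lay on 1 strand; 15557 genes had a strand, and the median share of tags on it was 99.0% in protein-coding genes. This strand was not checked against an annotated one; where the 2 differ, the tags counted are antisense and the first and last 1 kb are exchanged. Mettl3 was given its majority strand although it missed that share. Tags in same-strand overlaps were left out. Whole spans took the place of the exons first planned, so gene values include introns. The last 1 kb of a gene took the place of the 3' UTR. The interior, the gene without its first and last 1 kb, took that of the coding region. Tests of motifs and of predicted m6A were not run.

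Tags per gene were counted here and tested with limma 3.58.1 (voom, lmFit, eBayes, two-sided, Benjamini-Hochberg) in R 4.3.3. The test first planned, edgeR quasi-likelihood, was not used on the counts made here, and limma-voom was the fallback written with it. Library totals were scaled by a trimmed mean of M values, trimming 30% of M and 5% of A. A gene needed 10 tags in a library of median size in at least 2 samples and 15 tags in all. Of replicate pairs, only wild-type 2 and 3 showed no spread beyond sampling noise in a chi-square test, and their tags were summed. For shares their mean was used. The plan had set 3 libraries against 3, so this merge is a departure from it, chosen from the data. Balance was fitted with library, region and region by genotype. It took protein-coding genes above a minimum span with a mean of 10 tags per region. Windows of 100 nt with at least 60 tags were tested with diffSplice. Lists were tested with camera (correlation 0.01), with an estimated correlation, and with fry. Shares were compared by exact permutation over 10 arrangements. Counting used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

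Lists, markers, comparisons, the naming rule and most alternatives were fixed before the data were examined. After first results had been seen, the code was corrected to that wording in 5 places: a ribosomal protein pattern that had dropped most Rpl genes, an ambiguous synonym in the long noncoding list, extra filters on gene symbols, a limit of 1 named window per gene, and long noncoding genes in the window test. Named were Mettl3, Fmr1, Fxr1 and Fxr2; the 12 largest and 12 smallest log2 fold changes among called genes with a mean of at least 10 CPM (tags of a gene per 1000000 gene tags), no predicted-gene, Rik or pseudogene name, and all knockout libraries on one side of all wild-type libraries; the 3 members of each list with most tags, and each called member of the m6A and long noncoding lists; and 5 windows and 5 balance genes per direction by adjusted p. Some genes that this rule takes are not reported here. Mitochondrial genes were taken by chromosome, since the annotation writes them without a prefix.

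The functions were tested on simulated tag counts with 200 changed features. Over 15259 genes, 72% of those changed 1.5-fold and 95% of those changed 3-fold were recovered, and 0.0465% of unchanged genes were called. For the balance of 7254 genes the shares recovered were 29% and 99%, and for 121237 windows 19% and 98%. These counts were drawn with a dispersion of 0.001. With only 200 features changed, the adjusted cutoff is stricter than in the data, where 10127 of 15259 genes were called. The simulated shares of false and recovered calls therefore do not carry over to the data. Libraries held 5303830 to 18549813 tags. Thinned to the smallest sample, 9232 of the 10127 gene calls were tested and 7465 kept their call and direction, so part of the calls need the deeper libraries. Alternatives were other scaling and filters, leaving out each library, 1 tag per position, thinning to the smallest sample, scaling without the 50 genes with most tags, a replicate block, and other window and tag minimums. Chosen after seeing the data were the last 1 kb alone and the interior alone, each scaled to its own tags. The 6 libraries as separate samples, the comparison first planned, became an alternative once wild-type 2 and 3 had been summed.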

Results

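Individual-nucleotide crosslinking and immunoprecipitation (iCLIP) of FMRP, the RNA-binding protein encoded by Fmr1, was compared between mouse embryonic fibroblasts with and without Mettl3, the catalytic subunit of the m6A writer. The labels list 3 wild-type replicates given vehicle and 3 knockout replicates in which Cre-ERT2 was induced with 500 nM 4-hydroxytamoxifen for 8 days, so genotype and drug changed together. Each tag is 1 unique crosslinked RNA fragment. The wild-type libraries held 5303830, 9190681 and 10720892 tags and the knockout libraries 18549813, 17435889 and 6555991. Over 13715 genes, a chi-square test found no spread beyond sampling noise between wild-type replicates 2 and 3 (chi-square per degree of freedom 1.02, p = 0.0935), and they were counted as 1 sample, which left 2 wild-type and 3 knockout samples. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. RNA-seq libraries were not used here, so a change in the tags of a gene can come from its RNA level as well as from binding.

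Mettl3 itself had fewer tags per 1000000 tags in every knockout library. Its majority strand, the strand with more of the pooled tags, held 17.5, 17.6 and 17.1 tags per 1000000 tags in wild-type replicates 1 to 3 and 9.54, 10.3 and 9.15 in knockout replicates 1 to 3. The opposite strand held between 7.54 and 9.36 tags per 1000000 in wild type and between 7.71 and 8.24 in knockout. In the fit over all genes, Mettl3 (chromosome 14, 52294841 to 52308741, GRCm38) had a log2 fold change of -0.80 (SE 0.10, limma-voom adjusted p = 5.7e-11). Counted in the last 1 kb of the gene alone, the log2 fold change was -0.21 (limma adjusted p = 0.606). That fit was scaled to last-1-kb tags, a class whose share of tags in protein-coding genes was 0.734 of wild type. The last 1 kb of Mettl3, with 95 tags, held 9.89% of the gene's tags in wild type and 10.7% in knockout. The value of -0.21 therefore does not show a smaller loss there than over the whole gene. Of 14 bins of 1 kb along the gene, the bin from 52299841 to 52300840 lost most: it held 16.5% of the gene's tags in wild type and 4.49% in knockout. Its exact two-sided permutation test gave p = 0.2, the smallest that 2 samples against 3 allow, and an adjusted p of 0.467 over the 14 bins. The bin rests on 85 tags, and whether it covers the deleted exon was not determined.

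**Figure D1:**
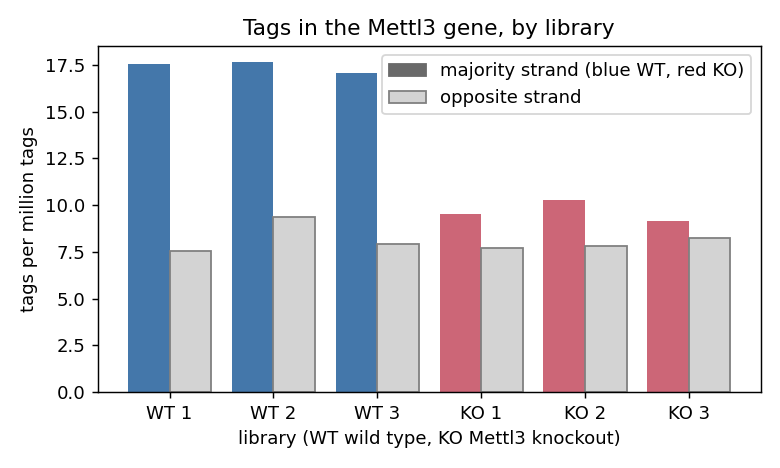
Tags in the Mettl3 gene per 1000000 tags, for each library; coloured bars are the majority strand (blue wild type, red knockout) and grey bars the opposite strand. The coloured bars lie at 17.1 to 17.6 in wild type and 9.15 to 10.3 in knockout, while the grey bars overlap between genotypes.

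To compare genes, tags on the majority strand were counted over whole gene spans, introns included, and scaled to CPM, the tags of a gene per 1000000 gene tags. The annotation used here gives no strand, so the tags counted for a gene can come from RNA antisense to it. Of 690 coding genes at least 2-fold higher, 206 had under 30 tags on both strands together in wild type, and 6 of the other 484 had most of their wild-type tags on the opposite strand. Of 15259 genes tested, 5043 were higher and 5084 lower in knockout, and 1215 and 1269 of these changed at least 2-fold. With a mean of at least 10 CPM, 368 and 316 of 9062 genes did. Counted in part of each gene and scaled to the tags of that part, 674 of 10187 were at least 2-fold lower in the last 1 kb. In the interior, without the first and last 1 kb, 744 of 13227 were. Some genes that rose most had almost no tags in wild type. Sh2d4a had 1, 8 and 4 tags in wild-type replicates 1 to 3 and 512, 491 and 188 in knockout. Ifi44, an interferon-stimulated gene, had 1, 9 and 5 tags against 270, 260 and 108. Opn5, an opsin, and Ifi207, of the interferon-inducible Ifi200 family, rose with log2 fold changes of 5.52 (SE 0.43) and 5.32 (SE 0.38). Mapk10, a Jun N-terminal kinase, rose 15.5-fold, and Iigp1, an interferon-inducible GTPase, rose 13.7-fold. Gda, guanine deaminase, rose 11.9-fold and Ccdc7b 10.5-fold. Boll, a germ-cell RNA-binding protein, went from 8.62 ± 1.84 (SD, n = 2) to 101 ± 0.763 (SD, n = 3) CPM. Xaf1 rose 10.2-fold, Svop 8.83-fold and the collagen gene Col27a1 7.95-fold. Adjusted p (limma) was at most 1.8e-17 for these genes, the value of Ifi44. For Mapk10, 123 of the wild-type tags lay on the opposite strand and 57 on the strand counted, so its rise is in RNA opposite to most of its wild-type RNA. Wild-type tags hardly tell the strand of Sh2d4a (13 counted, 12 opposite), Opn5 (12 and 11) or Gda (45 and 27), so knockout tags set it. Boll was counted on the strand that also held most of its wild-type tags (213 counted, 3 opposite), but whether that is the strand of the gene was not determined.

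Among genes lower in knockout, Lgr6, an R-spondin receptor, and Crabp1, which binds retinoic acid, had log2 fold changes of -2.51 and -2.50, with limma adjusted p of 2.4e-36 and 9.2e-42. Klhl1 went from 177 ± 2.56 (SD, n = 2) to 32.4 ± 0.915 (SD, n = 3) CPM. Nptx1, Skap1 and the collagen gene Col28a1 had log2 fold changes of -2.35, -2.31 and -2.19. For Skap1 and the other genes that fell, the strand counted was also not checked against an annotated one, so a fall can be in antisense RNA. Dgkk, a diacylglycerol kinase, had -2.07, and Syt1, a synaptotagmin, had -2.02. Mir29a, a microRNA, had -2.05, and its call was lost when each position was counted once (log2 fold change -0.50). It spans 88 nt and had 132, 275 and 313 tags in wild-type replicates 1 to 3. Counting each position once caps these values, so that setting cannot test its fall. The transfer RNA gene n-TAagc19 had -1.95 and is uncertain, because near-identical tRNA copies can share tags. Among the FMRP family, Fxr2 had a log2 fold change of -0.96 (SE 0.05), Fmr1 -0.43 (SE 0.03) and Fxr1 -0.17 (SE 0.04), with limma adjusted p of 1.1e-31, 2.9e-21 and 5.8e-05. The call of Fxr1 was lost when each position was counted once.

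Interferon-stimulated genes were higher in knockout as a group. All 26 measured members rose, 22 of them at least 2-fold, with a median log2 fold change of 1.62 (limma camera adjusted p = 5.4e-15, and adjusted p = 0.0458 with an estimated correlation). Adjusted over the list alone, 26 rose. Eif2ak2, the double-stranded RNA-activated kinase, went from 81.0 ± 0.529 (SD, n = 2) to 200.3 ± 4.41 (SD, n = 3) CPM, and Adar, an RNA-editing enzyme, from 62.1 ± 2.11 to 143 ± 5.78. Trim25 rose 1.55-fold. Of 4 measured macrophage markers, Cd68 and Csf1r rose, with log2 fold changes of 0.33 and 1.09, and 1 rose adjusted over the list alone. The marker list did not pass (limma camera adjusted p = 0.633).

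Proliferation genes and histones were lower. All 31 proliferation genes fell, with a median log2 fold change of -0.85 (limma camera adjusted p = 6.9e-19, and adjusted p = 0.0458 with an estimated correlation). Mki67 went from 982 ± 23.9 (SD, n = 2) to 518 ± 18.3 (SD, n = 3) CPM, Top2a from 545 to 237, and Anln from 474 to 211. All 52 measured histone genes fell, 44 at least 2-fold, with a median of -1.36 (limma camera adjusted p = 9.8e-14, but adjusted p = 0.0774 with an estimated correlation). The 3 with most tags, H1f4, H1f5 and H1f0, had log2 fold changes of -0.95, -0.93 and -0.82; H1f0 and H1f10 are replication-independent histones that the name pattern also took in. Adjusted over the list alone, 31 proliferation genes and 52 histones fell. Near-identical histone copies can share tags, so the 52 are not separate observations. Most of these genes are shorter than 1 kb and lie wholly in the last 1 kb, a class whose share of tags was 0.734 of wild type. In the interior, without the first and last 1 kb, the histone list lost its call (limma camera adjusted p = 0.0934), but most members have no tags there.

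Further lists passed camera with the preset correlation and lost the call with an estimated one. The estimate was -0.017, -0.045 and 0.0098 in the cholesterol, stress-response and p53 lists, not above the preset 0.01. A higher correlation among members therefore does not account for the calls these lists lost. In the translation, neuronal target, actin and matrix lists it was higher, at 0.059, 0.213, 0.025 and 0.019. Of 23 translation factors, 15 fell and 2 rose (median log2 fold change -0.51, limma camera adjusted p = 2.5e-07, and adjusted p = 0.0774 with an estimated correlation), with Eif4g1, Eif4g2 and Eif3a at -0.83, -1.05 and -0.57. Of 18 cholesterol genes, 16 fell and 1 rose, and 17 fell adjusted over the list alone (median -0.51, limma camera adjusted p = 0.00012, and adjusted p = 0.0774 with an estimated correlation); Srebf2 and Stard4 had -0.54 and -1.09. Of 21 stress-response genes, 15 fell and 2 rose (median -0.45, limma camera adjusted p = 0.00033, and adjusted p = 0.0774 with an estimated correlation); the chaperone genes Hsp90b1, Hspa5 and Calr had -0.54, -0.51 and -0.81. Of 30 genes known as neuronal FMRP targets, 19 fell and 9 rose (median -0.52, limma camera adjusted p = 1.2e-06, and adjusted p = 0.175 with an estimated correlation); Macf1 fell with -0.63, while Ank3 rose with 0.71 and Trio with 0.16. Of 20 actin and contractile genes, 11 fell and 5 rose (median -0.21, limma camera adjusted p = 0.0015, and adjusted p = 0.115 with an estimated correlation); Flna had -0.82 and Cald1 0.21. Of 31 matrix and fibroblast genes, 19 rose and 10 fell, 3 and 5 of them at least 2-fold, with a median of 0.28 and a mean of 0.11 (limma camera adjusted p = 0.0010, and adjusted p = 0.115 with an estimated correlation); the 3 with most tags, Fn1, Fbln2 and Col5a1, had 0.14, 0.28 and 0.57. Of 24 p53 targets, 13 rose and 4 fell (median 0.33, limma camera adjusted p = 0.0127, and adjusted p = 0.136 with an estimated correlation); Aen and Mdm2 had 0.96 and 0.12 and Ccng1 -0.21. Counted once per position, the matrix and actin lists also lost their calls (adjusted p = 0.0787 and 0.111), as did the p53 targets in the last 1 kb alone (adjusted p = 0.0863). Apart from the cholesterol genes, counts adjusted over the list alone were equal to these.

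**Figure D2:**
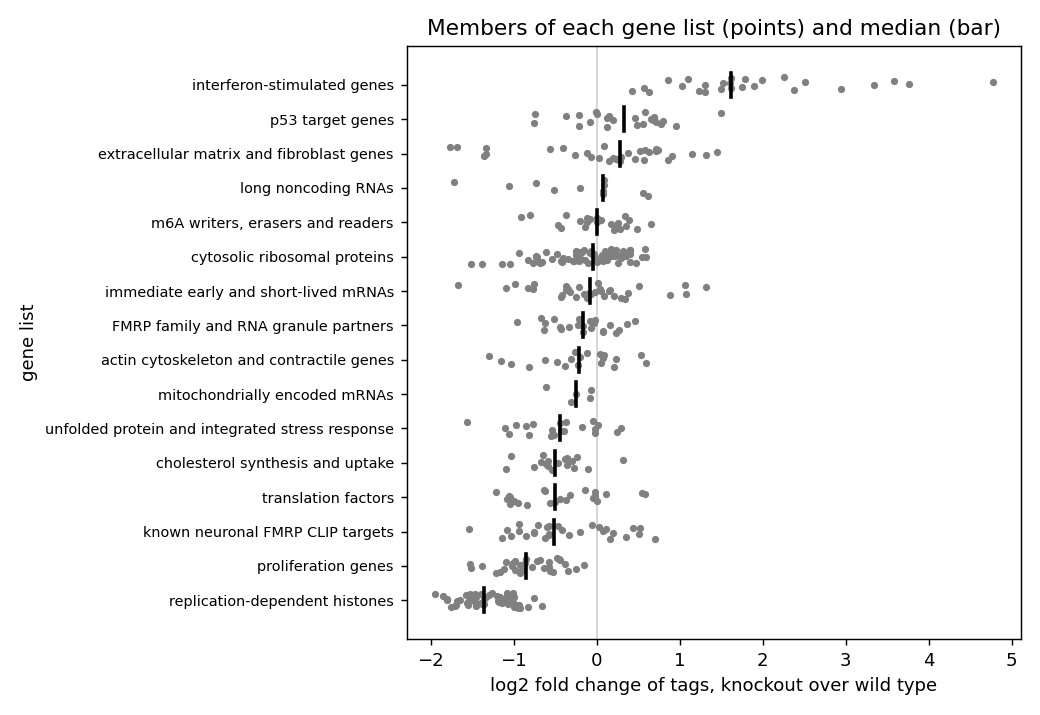
Log2 fold change of tags, knockout over wild type, for each measured member of the 16 gene lists (points) and the list median (bar). The interferon-stimulated genes have a median of 1.62, the proliferation genes of -0.85 and the histones of -1.36.

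The other lists did not pass camera with the preset correlation over whole genes, but some passed under an alternative. Of 23 genes for m6A writers, erasers and readers, 10 rose and 8 fell, and their median of 0.01 and mean of -0.01 differ in sign (limma camera adjusted p = 0.491). Ythdf2 and Igf2bp2, which encode readers, rose with log2 fold changes of 0.65 and 0.49, and Fto, an eraser, with 0.21. Zcchc4, Rbm15, Cbll1, Igf2bp3, Rbm15b, Ythdf3 and Ythdc1 rose with 0.39, 0.35, 0.34, 0.29, 0.25, 0.23 and 0.17. Besides Mettl3, Rbmx, Virma, Hnrnpa2b1, Mettl14, Hnrnpc, Igf2bp1 and Zc3h13 fell, with -0.91, -0.47, -0.43, -0.37, -0.20, -0.14 and -0.12. Of 11 long noncoding RNAs, Malat1, Tug1 and Neat1 rose with 0.62, 0.56 and 0.07, and Mir99ahg, Rian, H19 and Meg3 fell with -1.72, -1.05, -0.74 and -0.51 (limma camera adjusted p = 0.491); their median of 0.07 and mean of -0.25 differ in sign. Of 23 FMRP family and granule genes, 12 fell and 7 rose (limma camera adjusted p = 0.0744), with Atxn2 and Ago2 at 0.23 and 0.07 and Pum2 at -0.17. Of 76 ribosomal protein genes, 27 fell, 10 rose and 39 were not called, with a median log2 fold change of -0.04 (limma camera adjusted p = 0.091), and 9 rose adjusted over the list alone; the 3 with most tags, Rpl4, Rpl8 and Rps3, are among the 4 that fell at least 2-fold (the name pattern also took in Rps19bp1, which is not a ribosomal protein and was not called), with -1.38, -1.51 and -1.05. Of 34 immediate early genes, 15 fell and 9 rose (limma camera adjusted p = 0.774), with Fosl2 and Klf6 at 0.34 and 0.29 and Ccn1 at -0.12. Of 5 mitochondrial mRNAs, 3 fell (limma camera adjusted p = 0.153); ND2 and ND1 had -0.31 and -0.25, and CYTB, which did not pass, -0.08. In these lists the counts adjusted over the list alone were otherwise equal. Under alternatives, camera called the mitochondrial mRNAs lower with 1 tag per position (adjusted p = 0.0333). In genes as short and densely tagged as ND2 (positions 3914 to 4951), that count removes more tags from deeper libraries, so this call can come from depth. Camera also called the FMRP family and granule genes lower in the interior, without the first and last 1 kb (adjusted p = 0.0150). It called the long noncoding RNAs higher in the last 1 kb alone (adjusted p = 0.00082). The immediate early genes turned to higher in the last 1 kb alone (adjusted p = 0.0189). Over all alternatives with camera, adjusted p ranged from 0.0333 to 0.577, 0.0150 to 0.759, 0.00082 to 0.791 and 0.0189 to 0.954 for these 4 lists. The limma test fry, which does not set a list against other genes, passed the m6A, FMRP family, ribosomal and long noncoding lists (adjusted p = 0.0156, 0.0020, 0.00044 and 2.6e-05).

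Markers of other cell types were measured in few genes. The 3 epithelial markers, Krt19, Krt18 and Cldn4, fell with log2 fold changes of -2.69, -1.31 and -1.50 (limma camera adjusted p = 0.0753, and 0.0364 with 1 tag per position; 0.0364 to 0.688 over all alternatives; fry adjusted p = 0.00069). Of 7 neural markers, 2 fell, among them Map2 with -0.62 (limma camera adjusted p = 0.569, fry adjusted p = 0.0129). Of 3 endothelial markers, Esam rose with 1.72, and Kdr and Vwf did not pass, with -0.12 and -0.38 (limma camera adjusted p = 0.641). The 2 measured muscle markers, Ttn and Tnnt3, had 0.26 and -0.86, too few for a list test. Fcer1g, a macrophage marker that did not pass, had 0.21. Adjusted over the list alone, the counts of the epithelial, neural, endothelial and muscle markers were equal to these.

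Where tags lay also differed between genotypes. The last 1 kb of protein-coding genes held 5.48% ± 0.013 (SD, n = 2) of tags in wild type and 4.03% ± 0.045 (SD, n = 3) in knockout, and the first 1 kb 2.49% ± 0.073 and 2.05% ± 0.080. The ribosomal RNA repeat fell from 2.74% ± 0.195 to 1.32% ± 0.206, and small noncoding RNAs from 0.617% ± 0.0050 to 0.493% ± 0.022. The rest of protein-coding genes, mostly intron by length, rose from 75.3% ± 0.073 to 76.7% ± 0.102. The opposite strand of genes rose from 4.07% to 4.55%, other genes from 3.25% to 3.84%, the 5 kb beside genes from 3.62% to 4.10%, and sequence farther from any gene from 2.27% to 2.77%. Same-strand overlaps held 0.168% and 0.154%. In each of these 10 classes all 3 knockout libraries lay on one side of all 3 wild-type libraries, and each exact two-sided permutation test gave p = 0.2, the smallest this design allows. Counted once per position, the rest of protein-coding genes turned to a difference of -0.38 percentage points.

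**Figure D3:**
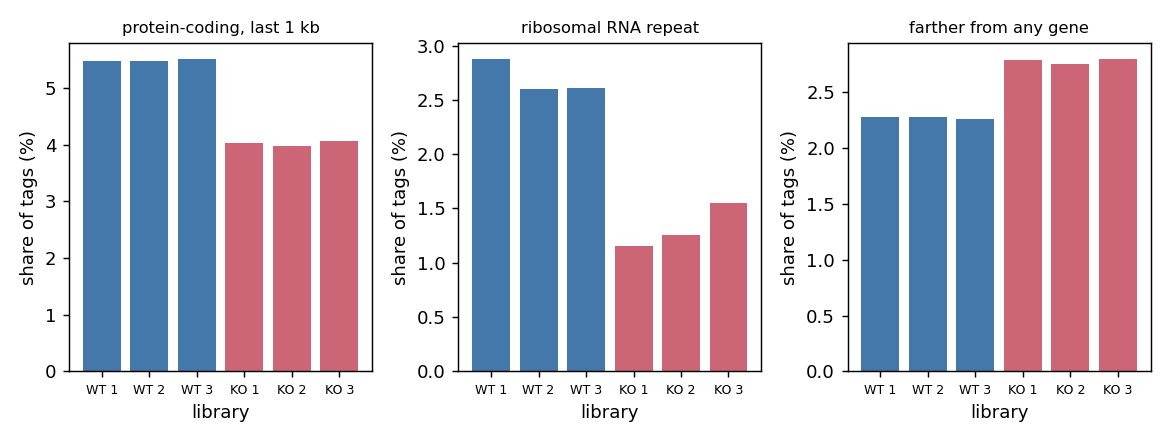
Share of tags (%) in each library for the last 1 kb of protein-coding genes, the ribosomal RNA repeat and sequence over 5 kb from any gene; blue bars are wild type and red bars knockout. The first falls from 5.48% to 4.03%, the second from 2.74% to 1.32%, and the third rises from 2.27% to 2.77%.

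Within genes, the balance moved away from the 3' end. Over 7271 protein-coding genes, the log2 ratio of tags in the last 1 kb to tags in the interior changed by a median of -0.34, with 2456 genes lower and 294 higher (limma adjusted p under 0.05). The shares that follow are of the tags in the last 1 kb and the interior together, without the first 1 kb. Tpm1, a tropomyosin gene (chromosome 9, 67022590 to 67049672), went from 22.6% ± 0.426 (SD, n = 2) in the last 1 kb to 13.0% ± 0.133 (SD, n = 3). Actn1, an actinin gene (chromosome 12, 80167542 to 80260420), went from 12.7% to 6.29%. Sptbn1, Myof and Anxa2 had log2 changes of the balance of -0.70, -1.15 and -0.95. Hjurp, a centromere histone chaperone gene, went from 2.63% to 8.61%. Slfn9, Zfp386, Trps1 and Gm45871 had log2 changes of 4.11, 2.19, 2.10 and 2.85. Their wild-type shares were small, at 0.133% ± 0.189 (SD, n = 2), 3.49% ± 0.633, 0.320% ± 0.0056 and 3.10% ± 1.99. In knockout the shares were 3.23%, 14.8%, 1.34% and 21.9%. The change of Slfn9 thus rests on a wild-type value near 0. Set against the median shift, 782 genes were lower and 774 higher.

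Single 100-nt windows were then set against the rest of their gene. Of 121237 windows in 4414 protein-coding genes, 5068 were lower and 7574 higher in knockout relative to their gene (limma diffSplice, adjusted p under 0.05). Without wild-type replicate 3 these counts were 1630 and 1570, without wild-type replicate 2 they were 2109 and 2561, and without wild-type replicate 1 the higher count was 4926. The last 1 kb held 9.87% of windows tested, 10.9% of those lower and 5.92% of those higher. In Nedd4, a ubiquitin ligase gene, the windows on chromosome 9 that start at 72721301, 72721501 and 72726401 went to 0.605, 0.589 and 0.492 of their wild-type level relative to the gene. The window at 72663001, 720 nt from the 5' end of Nedd4, rose 2.83-fold. Windows in Pkm (chromosome 9, 59665301 to 59665400) and Tpm1 (chromosome 9, 67047801 to 67047900) went to 0.406 and 0.437. Windows in Iars (chromosome 13, 49693701 to 49693800), Eif4g1 (chromosome 16, 20690001 to 20690100), Srrm2 (chromosome 17, 23812001 to 23812100) and Trrap (chromosome 5, 144771401 to 144771500) rose 6.28-fold, 3.91-fold, 3.14-fold and 2.22-fold. Whether these windows are exonic or intronic was not determined, since gene spans without exons were used.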

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

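Leaving out 1 library, 9722 to 10127 of the 10127 gene calls were tested and 8879 to 9843 kept their call and direction; none was called in the other direction there or under the other scalings. With 1 tag per position, 9138 of 10006 calls tested were kept and 7 were called in the other direction. In the last 1 kb alone, scaled to the tags of that part, only 3953 of 7310 were kept and 200 were called in the other direction. In protein-coding genes the share of tags in that part was 0.734 of wild type, so its scale lies above that of whole genes. Part of the lost and reversed calls can come from this change of scale. In the interior, without the first and last 1 kb, 7890 of 8971 were kept and 8 were called in the other direction. Leaving out 1 library gave 4462 to 5041 genes higher, 4584 to 5042 lower, 1057 to 1208 at least 2-fold higher and 1093 to 1293 at least 2-fold lower; without wild-type replicate 1 the remaining wild-type sample is assumed to vary like the knockout. The log2 fold change of Mettl3 ranged from -0.85 to -0.77, and its bin with the largest loss from -13.2 to -8.17 percentage points. Over the same settings 3 lists were higher and 7 lower, the median balance lay between -0.36 and -0.34, balance calls between 1840 and 2280 lower and 205 and 264 higher, and window calls between 1630 and 4658 lower and 1570 and 6613 higher. With a mean of at least 10 CPM, 368 genes were at least 2-fold higher and 316 lower, of 9062 tested. In the last 1 kb alone, chosen after seeing the data, 2382 genes were higher, 2387 lower and 674 at least 2-fold lower, of 10187 tested. Mettl3 lost its call there, at -0.21 on the scale of that part. In the interior, 744 were at least 2-fold lower. In the last 1 kb alone the immediate early list turned to higher (adjusted p = 0.0189). An estimated correlation left 1 list higher and 1 lower, and fry gave 5 higher. A minimum of 30 tags per region moved the median balance to -0.37. Windows of 50 nt gave 2386 lower and 3610 higher, windows of 200 nt 10348 and 14922, and at least 150 tags 978 and 1366, with fewer or more windows tested. With 6 libraries as separate samples, the comparison first planned, window calls were 3366 and 4604. Counted once per position, the share in the rest of protein-coding genes turned to -0.38 percentage points. Where no construction shows it, the cause was not tested. Deviations of same-numbered libraries from their genotype means correlated at -0.026, 0.014 and -0.0019. Replicates differed by little more than sampling noise (chi-square per degree of freedom 1.02 to 1.56). Such low values can therefore arise with or without pairing, and whether numbers pair the libraries stays open. A replicate block over 6 libraries gave 3322 window calls lower and 4299 higher and moved no other count by over 1.5 times. Not run were a second count-model test, coding tags only, motif density and predicted m6A.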

Other observations

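The tests of scaling, macrophages, depth, chromosome parts and other splits were chosen only after the results were seen, and chromosomes 9 and 10 were picked from medians already seen. Classes of RNA moved apart. Of 1681 long noncoding RNA genes tested, 692 rose and 195 fell, with a median log2 fold change of 0.38. Of 143 transfer RNA genes, 108 fell and 0 rose, with a median of -1.20, and of 187 small nucleolar RNA genes, 134 fell and 3 rose. Near-identical copies can share tags in the small RNA classes. Of 779 pseudogenes, 456 fell and 106 rose; tags of their parent genes can align there. Of 18 Hox genes tested, a group chosen after its values were seen, 11 rose and 3 fell: 5 of 6 rose in the Hoxb cluster, 6 of 9 rose and 2 fell in Hoxc, and 0 of 3 rose and 1 fell in Hoxa.

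Interferon-stimulated genes rose together, and a scaling factor shared by all genes cannot give this: the median log2 fold change of the list lay 1.62 above that of all genes, a difference that no scaling changes. Macrophages in the knockout cultures stay open: of 12 listed markers, only 4 met the strand and tag minimums. These 4 had a median log2 fold change of 0.27 and at most 7.62 CPM in knockout (Cd68). They are too few to exclude macrophages. Drug and Cre activity cannot be told apart from loss of Mettl3, because 0 wild-type samples were given 4-hydroxytamoxifen. Loss of Mettl3 therefore remains an untested explanation.

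The lower share at 3' ends is not given by a linear trend with depth alone. Adjusted for the trend of the median log2 balance with log2 depth within genotypes, knockout lay -0.34 from wild type over the 5 samples (95% interval -0.363 to -0.310, 2 residual degrees of freedom), and without adjustment -0.36. The interval takes the trend to be equal in both genotypes. A lower share of spliced RNA in the knockout libraries stays open. Genes with a larger wild-type share in the last 1 kb lost more tags (Spearman -0.20), but the lower balance gives this relation by arithmetic, so it decides nothing. Weaker FMRP binding at 3' ends stays open as well.

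Several chromosomes had medians away from 0. The median log2 fold changes were -0.15 on chromosome 9, -0.11 on 18 and -0.23 on X, and 0.12, 0.11 and 0.11 on 4, 5 and 10; the 19 mitochondrial genes tested had -0.31. With chromosomes 9 and 10 split in gene order into 3 parts each, 6 of the 6 parts lay on their chromosome's side of 0. Since these 2 were picked for their medians, this does not decide whether a few regions give the shift. Chromosome copy number was not tested.

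With 6 libraries as separate samples, 9776 genes were called between genotypes, and the highest of the other splits gave 0; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05.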
